A study of Saccharomyces cerevisiae with 41 samples.

How the data were processed

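The values used are estimated counts, 1 per feature and library, in 3 deposited tables: oligo d(T)-selected RNA (10 libraries), RNA depleted of ribosomal RNA (13 libraries) and single 3′ tags (18 libraries). Per the labels' protocols, cells grew at 25 °C and were moved to 37 °C for 90 min. RNA for the first 2 tables came from frozen cell powder and was made into stranded libraries read as pairs of 50 bases. RNA for the 3′ tag table came from a column kit, its libraries were read as single reads of 90 bases, and adapters, poly(A) stretches and the first bases were trimmed off. Per the submitters' processing notes, reads were trimmed with Trimmomatic (0.39 for the first 2 tables, 0.38 for the 3′ tags), and the deposited estimated counts come from Salmon 0.12.0 against features of the sacCer3 (R64) build. The notes also name bedtools, DESeq and DESeq2 1.26.0, and no output of these was used here. The notes do not say how overlapping features or paralogs were treated. The deposited estimated counts were not whole numbers and not scaled: they were at least 0 and their totals differed between libraries. Replicate libraries were checked for copies, and 0 identical pairs were found.

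Each column was matched to a sample by its title or by the strain, vector and replicate in its name, and 0 columns were left out. The labels of csl4 ribo-depleted replicate 1 describe oligo d(T) selection, while its title and its table say ribo-depleted, and it was kept in that table. Feature names were matched to the R64 annotation: 5882 of 6542 ORFs had an entry, and 5853 of these had the same chromosome, start and end. Of the ORF spans 97.11% were multiples of 3. The spans run over the genome, so that those of ORFs with introns, such as RPS14A, include the introns.

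Estimated counts were rounded to whole numbers. Tests were edgeR (4.0.16) quasi-likelihood F-tests in R 4.3.3, 2-sided, with trimmed mean of M-values (TMM) scaling, edgeR's filter on low counts by group, and all groups of a table in 1 fit. The filter left 10464 features in oligo d(T) RNA, 10564 in ribo-depleted RNA and 6369 in 3′ tags, and 10790 for the fit of the first 2 tables together. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all features tested in a comparison. Comparisons were each mutant against the control within a table, the Pab1 vector against the empty vector within each strain, the interaction of strain and vector, and the interaction of strain and selection (oligo d(T) change minus ribo-depleted change). Fold changes are log2 ratios, CPM values are counts scaled to library size after TMM scaling, and errors are standard errors (SE) of fold changes or standard deviations (SD) of CPM. A gene with a group at 0 counts has its fold given as a bound against 3 counts per library, and list medians are also given with such genes at that bound.

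Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with adjusted p-values over the lists of a comparison, and again with an estimated correlation. Where the text gives no second p, the call held with an estimated correlation. The 26 lists covered ribosomal proteins, ribosome biogenesis, histones, proteasome, phosphate starvation, general stress genes of the Msn2/4 type, heat shock chaperones, amino acid biosynthesis, G1/S genes, mating pheromone response, alpha-specific genes, snoRNAs and their H/ACA and box C/D classes, CUTs and NUTs. The 10 further lists were the 7 genes followed by name, RNA exosome and cofactors, poly(A) binding and mRNA export, Nrd1-attenuated or exosome-regulated mRNAs, meiotic genes, selection markers, other stable noncoding RNAs, rRNA with its spacers, ST features and features numbered with F or R. A list needed 3 tested members. The lists, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined, except where the text says that a choice was made afterwards. The subsets of features that overlap no other feature, the haploid-specific list and the genes HMRA1 and HMLALPHA1 were added afterwards. By that rule the text names the 7 genes CSL4, DIS3, RRP6, ENP1, SRM1, PAB1 and NAB2, the genes with the largest rises and falls among those called with a mean of at least 10 CPM, and the 3 members of a called list with the smallest adjusted p, from which the text takes those that add to the account.

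Overlaps of calls between mutants were set against the product of the 2 numbers of calls over the features tested, and against groups simulated with no change that share the same control libraries (5 draws). The control libraries were too few to be split between mutants. Each test was tested on simulated data. Most genes were left unchanged there, 10172 of 10408 in the first case below, so errors from scaling are not covered. In data made like csl4 and control in oligo d(T) RNA (10408 genes) 56.1% of 1.5-fold, 64.6% of 2-fold and 87.7% of 4-fold changes were called, with 6 false calls. In data made like csl4 and control in 3′ tags (6199 genes) these shares were 12.1%, 25.4% and 67.7%, with 2 false calls. For the interaction of enp1 and Pab1 (6246 genes) 10.6% of 2-fold and 30.8% of 4-fold changes were called.

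The alternatives were DESeq2 1.42.0 in place of edgeR, median-ratio scaling, scaling on ORFs alone, no filter on low counts, the replicate number as a block, the compared groups alone in the fit, leaving out each library in turn, an estimated correlation for lists, and calls of at least 2-fold for shared changes.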

Results

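The series measured RNA from budding yeast (Saccharomyces cerevisiae, vegetative cells, given in the labels as strain background BY4741) that grew at 25 °C and were then held at 37 °C for 90 min. A control strain was set beside strains labelled csl4-ph, enp1-1, srm1-ts, dis3-1 and rrp6 deletion. CSL4, DIS3 and RRP6 encode subunits of the RNA exosome, the complex that degrades and trims nuclear RNA from its 3′ end. ENP1 encodes a factor for the making of the small ribosomal subunit, and SRM1, also known as PRP20, encodes the nucleotide exchange factor of the Ran GTPase that drives nuclear transport. The 41 libraries came in 3 tables. Oligo d(T)-selected RNA was measured in 10 libraries (control n = 3, csl4 n = 3, enp1 n = 2, srm1 n = 2). RNA depleted of ribosomal RNA was measured in 13 libraries (control n = 2, csl4 n = 3, and n = 2 each for enp1, srm1, dis3 and rrp6 deletion). Single 3′ tags were measured in 18 libraries, with n = 3 in each of 6 groups: control, csl4 and enp1, each carrying an empty vector or a vector for Pab1 fused to GFP, a fluorescent protein. PAB1 encodes the main cytoplasmic poly(A)-binding protein and NAB2 a nuclear one, and both were followed with the mutated genes.

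The oligo d(T) libraries held 15589670 to 33251600 estimated counts, the ribo-depleted libraries 12795066 to 32142495 and the 3′ tag libraries 1458382 to 3027707. In the 3′ tag libraries 50.01% to 68.37% of the counts fell on TAR1, an open reading frame inside the ribosomal DNA (XII 454696–455070), so that 472470 to 837691 counts lay outside the ribosomal DNA. A gene with no counts was held to a floor of 3 counts per library, which is 0.0847 to 0.264 CPM (counts scaled to library size) in the oligo d(T) libraries, 0.0866 to 0.313 CPM in the ribo-depleted libraries and 1.01 to 1.94 CPM in the 3′ tag libraries. These floors cover counting error only. The feature set of 11587 entries held 6542 open reading frames (ORFs), 924 cryptic unstable transcripts (CUTs, short RNAs that the exosome degrades), 1526 Nrd1-unterminated transcripts (NUTs, RNAs that extend when termination by Nrd1 is lost), 846 features named ST, 1656 features numbered with F or R, 76 snoRNAs and smaller classes. ORFs were given by genomic spans, introns included, that equalled the annotated start and end in 5853 of the 5882 ORFs with an entry. How many 3′ tags lay past the end of their ORF was not measured. Of the CUTs 62.55% overlapped an ORF on either strand, and values of overlapping features and of paralogs are uncertain because reads may be divided between them. Every p-value measures the spread between these libraries only. For each gene named as having risen or fallen against the control or the empty vector, all libraries of 1 group lay beyond all libraries of the other. Coordinates are those of the sacCer3 (R64) build, counted from 1.

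The genes altered in each strain were read as a check on the labels, although only the deletion is expected to lower its transcript. RRP6 (YOR001W) fell by 2.24 ± 0.0528 (SE) on the log2 scale in the ribo-depleted libraries labelled rrp6 deletion, to 39.04 ± 1.27 CPM (SD, n = 2) from 184.7 ± 7.06 CPM in the control (n = 2), so that RRP6 reads remained. CSL4 (YNL232W, XIV 214923–215801) stood at 78.18 ± 2.39 CPM in csl4 against 79.33 ± 6.33 CPM in the control in oligo d(T) RNA, a log2 fold change of −0.02 (adjusted p = 0.742) that turned to 0.03 with median-ratio scaling. It was called higher with scaling on ORFs, at 0.32, and without control oligo d(T) replicate 1, at 0.143. In ribo-depleted RNA its log2 fold change was −0.05 (adjusted p = 0.395), which turned to 0.11 with median-ratio scaling and was called higher with scaling on ORFs, at 0.44. ENP1 (YBR247C) rose in enp1 by 0.55 ± 0.0408 in oligo d(T) RNA and by 0.15 in ribo-depleted RNA. The latter rise was not particular to enp1, since ENP1 rose by 0.56 in ribo-depleted srm1. DIS3 (YOL021C) stood at 276.2 ± 3.96 CPM in dis3 against 264.6 ± 4.45 CPM in the control, a difference of 0.06 with an adjusted p of 0.0737. DIS3 was called higher in dis3 with median-ratio scaling, at 0.19, and with scaling on ORFs, at 0.48. SRM1 (YGL097W) overlaps another feature, and its difference in srm1 was 0.99 (adjusted p = 0.0552; called at 1.03 with median-ratio scaling) in oligo d(T) RNA and 1.70 (adjusted p = 0.0024) in ribo-depleted RNA. The rise was not particular to srm1: in ribo-depleted RNA, where the 2 control libraries stood at 30.17 and 8.046 CPM, SRM1 also rose by 2.12 in csl4, by 1.86 in enp1 and by 1.14 in rrp6 deletion, where the call ended without rrp6 deletion replicate 1 (0.96). In oligo d(T) RNA it fell by 1.34 in csl4.

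Mating-type and marker genes separated the strains into 3 kinds, and these facts stand beside every gene group described here. The labels give the background BY4741 for all strains, control and csl4 included, although these genes differ between them. Which strains depart from that background was not tested, and the control may be among them. In ribo-depleted RNA the control held 679.9 ± 17.1 CPM of MF(ALPHA)1, the alpha pheromone, and csl4 held 224.9 CPM. The log2 fold change of MF(ALPHA)1 was −10.87 in enp1, −6.99 in srm1, −10.19 in dis3 and −10.73 in rrp6 deletion. STE2, the alpha-pheromone receptor made by a cells, stood at 7.374 CPM in the control and at 426 CPM in enp1, 62.65 CPM in srm1 and 352.3 CPM in dis3. The same strains differed at selection markers: LYS2, a lysine biosynthesis gene, was at 0.5413 CPM in the control and at 651.2 CPM in enp1, 681.6 CPM in srm1, 395.4 CPM in dis3 and 455.9 CPM in rrp6 deletion. MET17, a sulfur assimilation gene, stood at 538.9 ± 12.4 CPM in the control and 91.17 CPM in csl4, and under 1 CPM in the other 4 strains. Chosen after its values were seen, HMRA1, the a1 transcript, was at 23.66 ± 1.66 CPM in rrp6 deletion, 12.47 ± 1.21 CPM in dis3, 8.243 ± 0.427 CPM in enp1 and 5.157 ± 0.0497 CPM in srm1, and at 0 counts in control and csl4. HMLALPHA1, the alpha1 transcript, also chosen afterwards, stood at 75.83 CPM in the control, 23.94 CPM in csl4 and 6.001 CPM in rrp6 deletion.

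**Figure D1:**
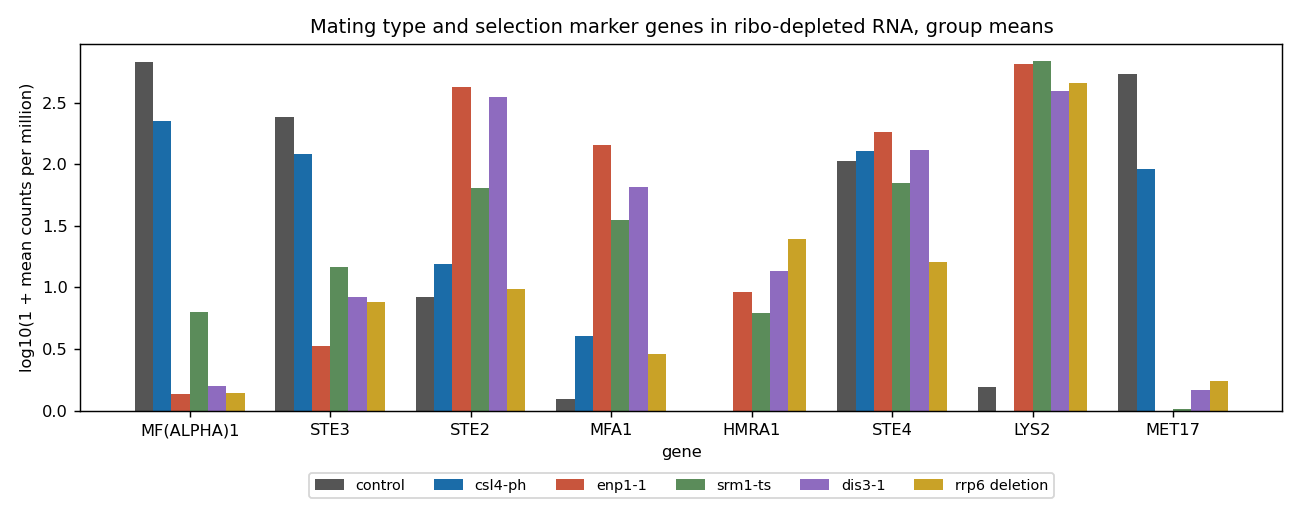
Mean level of 8 mating-type and marker genes in ribo-depleted RNA, with each bar the log10 of 1 plus the mean CPM of a strain (n = 2 or 3). Control and csl4 hold MF(ALPHA)1 and MET17 with LYS2 under 1 CPM, and the other strains hold LYS2 with MET17 under 1 CPM.

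Oligo d(T)-selected libraries of csl4 (n = 3) and control (n = 3) were compared to ask how RNA with poly(A) tails differed with the exosome subunit allele. Histone genes fell: HTA2, a histone H2A gene, fell by 4.37 ± 0.0431 on the log2 scale, from 942 ± 39.1 to 45.65 ± 1.79 CPM, and HHF1, a histone H4 gene, by 3.20. Ribosomal protein genes fell broadly, RPL2A by 1.98 ± 0.0242 (adjusted p = 3.46e-10). PAB1 (YER165W, V 510373–512106) fell by 1.11 ± 0.0523, from 1566 ± 115 to 724.2 ± 27.6 CPM, with an adjusted p of 1.77e-07. NAB2 (YGL122C, VII 278946–280523) fell by 0.41, but with scaling on ORFs its log2 fold change of −0.07 was not called. Among noncoding RNAs, snR189, an H/ACA snoRNA that guides pseudouridylation, rose by 4.17 ± 0.123 from 6.474 ± 1.32 to 117.5 ± 5.13 CPM. The transcript CUT_XII_109242_109666 rose by 4.64 ± 0.143.

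By list, all 9 tested histone genes fell, with a median of −3.14 (camera adjusted p = 2.61e-05; adjusted p = 0.136 with an estimated correlation). Of 135 ribosomal protein genes 125 fell and 7 rose, median −1.85 (1.9e-21; adjusted p = 0.155 with an estimated correlation). Of 32 proteasome genes 2 rose and 30 fell, among the latter PRE2 by 1.33 ± 0.0267, with a median of −0.87 and an adjusted p of 7.72e-08. Of 11 genes of the phosphate starvation response 10 fell, among them PHO12, an acid phosphatase, by 3.73 ± 0.0552 and VTC3, of the polyphosphate synthase, by 2.21, with an adjusted p of 0.000263. Of 24 heat shock chaperone genes 4 rose and 19 fell, among the latter HSP104 by 2.20 ± 0.0343 and HSP42 by 2.24, with an adjusted p of 0.00115 (adjusted p = 0.0803 with an estimated correlation). Of 20 general stress genes of the Msn2/4 type 17 fell, median −1.86 (camera adjusted p = 2.91e-06; adjusted p = 0.125 with an estimated correlation). For each of these lists the number adjusted over the list alone equalled that over all genes.

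Of 45 tested snoRNAs 36 rose and 2 fell (37 and 2 adjusted over the list alone), with a median of 3.12, or 2.94 with the 9 members that had a group at 0 set to their bound. All 24 H/ACA snoRNAs rose, snR10 by 3.52, though snR10 overlaps another feature. The spliceosomal RNA LSR1 rose by 1.67 ± 0.0921. Of 739 CUTs 429 rose and 70 fell (419 and 69 adjusted over the list alone), with a median of 1.75, or 1.64 at the bound. Among 90 CUTs that overlap no other feature 85 rose. Of 1457 NUTs 877 rose and 319 fell (880 and 320 adjusted over the list alone). Camera adjusted p-values were 1.06e-08 for snoRNAs, 1.58e-08 for CUTs and 3.74e-07 for NUTs, and these calls held with an estimated correlation. Counts in rRNA features made up 6.185 ± 0.315% in csl4 and 2.798 ± 1.16% in the control.

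Among 18 genes of the mating pheromone response 14 rose and 2 fell (the same adjusted over the list alone), with an adjusted p of 0.00408 (adjusted p = 0.0634 with an estimated correlation). FUS2, needed for cell fusion, rose by 1.84 and FIG2, a cell wall adhesin of mating, by 1.67. All 4 alpha-specific genes fell, MF(ALPHA)2 by 4.89 and SAG1, the alpha-agglutinin, by 2.96, with an adjusted p of 0.00624 (adjusted p = 0.0634 with an estimated correlation). Of 10464 tested features 3998 were higher in csl4 and 4148 lower. Scaling on ORFs shifted the median of all genes by 0.34 and gave 5063 higher and 3127 lower.

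Oligo d(T)-selected libraries of enp1 (n = 2) and control (n = 3) asked the same of the ribosome biogenesis allele. Ribosomal protein genes fell: RPS3, of the small subunit, by 2.94 ± 0.0406 on the log2 scale, from 3001 to 391.2 CPM (adjusted p = 7.46e-10), and RPL2A by 2.19. PAB1 fell by 1.17 and NAB2 by 0.46, while DIS3 rose by 0.98 ± 0.0435. PHO12 fell by 4.28 and PHO89, a phosphate transporter, by 3.65. HTA2 fell by 2.54 and HTB1, a histone H2B gene, by 2.16. CUT_XII_109242_109666 rose by 4.61 and snR85 by 1.63 ± 0.113, from 4.802 to 14.84 CPM.

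Of 135 ribosomal protein genes 131 fell and 4 rose, median −1.97 (camera adjusted p = 5.97e-25; adjusted p = 0.178 with an estimated correlation). All 9 histone genes fell, with an adjusted p of 0.000173 (adjusted p = 0.178 with an estimated correlation). All 11 phosphate starvation genes fell, with a median of −3.65 and an adjusted p of 0.000206. Of 32 proteasome genes 30 fell and 2 rose, median −0.99, with an adjusted p of 2.29e-07. Of 24 heat shock chaperone genes 5 rose and 16 fell, among the latter HSP104 by 2.23, with an adjusted p of 0.0154 (adjusted p = 0.178 with an estimated correlation). These counts were the same adjusted over the list alone. Of 45 snoRNAs 25 rose and 3 fell, both ways of adjusting alike, with a median of 1.34 and an adjusted p of 0.000872 (adjusted p = 0.0534 with an estimated correlation). Of 739 CUTs 377 rose and 86 fell (364 and 82 adjusted over the list alone), with a median of 1.28, or 1.30 at the bound, and an adjusted p of 5.39e-06.

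Of 18 mating pheromone genes 11 rose and 1 fell in enp1, the same adjusted over the list alone, with an adjusted p of 0.00465 (adjusted p = 0.071 with an estimated correlation). The list includes a-specific genes, and of these STE2 rose by 5.85 and MFA1, an a-pheromone gene, by 6.65. All 4 alpha-specific genes fell (median −6.40, adjusted p = 0.00183), and MF(ALPHA)1 fell by 12.04 to 0.4017 CPM, the same adjusted over the list alone. LYS2 was at least 1869-fold higher, at 456.5 ± 4.51 CPM against 0 counts in the control. In all 3956 features were higher in enp1 and 4034 lower. Scaling on ORFs shifted the median of all genes by 0.295 and gave 4834 higher and 3288 lower.

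Oligo d(T)-selected libraries of srm1 (n = 2) and control (n = 3) asked how poly(A) RNA differed with the allele of the Ran exchange factor. Among heat shock chaperone transcripts, HSP78, of the mitochondrial matrix, rose by 3.20 ± 0.041 on the log2 scale, from 409.2 ± 6.59 to 3752 ± 44.2 CPM. HSP26 rose by 5.79 and SSA4, an Hsp70, by 2.80, and both overlap another feature. HRP1, a nuclear RNA-binding protein of 3′ end formation, rose by 3.56 ± 0.0371, from 417.7 ± 16.4 to 4913 ± 111 CPM. NAB2 rose by 1.52 ± 0.056, from 256.7 to 735.4 CPM, and PAB1 fell by 2.01 ± 0.0623. RPS20, of the small ribosomal subunit, fell by 4.77 ± 0.0585, from 3199 to 117.4 CPM, and HOM2, of methionine and threonine biosynthesis, by 3.94.

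Of 24 heat shock chaperone genes 19 rose and 2 fell, with a median of 0.99 and an adjusted p of 0.000852 (adjusted p = 0.0908 with an estimated correlation). Of 135 ribosomal protein genes 124 fell and 8 rose, median −1.51 (camera adjusted p = 1.43e-19; adjusted p = 0.271 with an estimated correlation). Of 12 G1/S cell cycle genes 1 rose and 11 fell, among the latter CLN2, a G1 cyclin, by 2.89, with an adjusted p of 0.00772 (adjusted p = 0.0908 with an estimated correlation). Of 11 phosphate starvation genes 8 fell, with an adjusted p of 0.0126 (adjusted p = 0.0908 with an estimated correlation). These counts were the same adjusted over the list alone. Of 739 CUTs 266 rose and 159 fell (254 and 153 adjusted over the list alone), with a median of 0.25, or 0.49 at the bound, and the list was not called, with an adjusted p of 0.214. Of 45 snoRNAs 25 fell and 2 rose (24 and 2 adjusted over the list alone), with a median of −1.52 and an adjusted p of 0.0295 (adjusted p = 0.194 with an estimated correlation). That call ended without the filter on low counts, at −0.18, and with the compared groups alone, at −1.52.

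All 4 alpha-specific genes fell in srm1, MF(ALPHA)1 by 7.83, the same adjusted over the list alone, with an adjusted p of 0.00772 (adjusted p = 0.0908 with an estimated correlation). MFA1 rose by 5.34. LYS2 was at least 1933-fold higher and MET17, which overlaps another feature, at least 3180-fold lower. In all 4108 features were higher in srm1 and 3949 lower, and scaling on ORFs shifted the median of all genes by 0.141.

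Ribo-depleted libraries of csl4 (n = 3) and control (n = 2) asked how total RNA outside the ribosomal RNA differed, whether or not it carried a poly(A) tail. PAB1 fell by 1.03 ± 0.0296 on the log2 scale, from 1537 to 751.1 CPM. NAB2 rose by 1.28 ± 0.0323, from 246.6 ± 2.48 to 596.9 ± 12.9 CPM. The H2B gene HTB2 fell by 3.01 and HHF1 by 2.58. RPL6A, of the large ribosomal subunit, fell by 1.64 ± 0.0204 and KRR1, a ribosome assembly factor, by 2.17. HIS4, of histidine biosynthesis, fell by 2.34 and TPS2, of trehalose synthesis, by 2.18. CUT_XII_109242_109666 rose by 3.80 ± 0.0827, from 2.664 ± 0.221 to 37.36 ± 1.25 CPM.

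Of 136 ribosomal protein genes 124 fell and 9 rose in ribo-depleted csl4, median −1.56 (camera adjusted p = 5.43e-18; adjusted p = 0.314 with an estimated correlation). Of 41 ribosome biogenesis genes 38 fell and 1 rose, median −0.90, with an adjusted p of 1.81e-08. All 32 proteasome genes fell, median −0.83 (camera adjusted p = 1.81e-08; adjusted p = 0.105 with an estimated correlation). All 9 histone genes fell, median −2.31 (camera adjusted p = 4.96e-05; adjusted p = 0.105 with an estimated correlation). Of 19 amino acid biosynthesis genes of the Gcn4 type 16 fell and 1 rose, median −1.03, with an adjusted p of 0.000473 (adjusted p = 0.254 with an estimated correlation). These counts were the same adjusted over the list alone. Of 735 CUTs 424 rose and 63 fell (412 and 61 adjusted over the list alone), with a median of 2.10, or 1.92 at the bound, and an adjusted p of 4.15e-10. Of 11 phosphate starvation genes 6 rose and 3 fell, the same adjusted over the list alone, and the list was not called, with a median of 0.29 and an adjusted p of 0.712. CUT features took 1.069 ± 0.0155% of counts in csl4 and 0.2937 ± 0.00554% in the control. Of 57 snoRNAs 30 fell and 13 rose, the same adjusted over the list alone, and the list was not called, with a median of −0.42 that was 0 with scaling on ORFs and an adjusted p of 0.223. MF(ALPHA)1 fell by 1.60 beside these groups. In all 3743 features were higher and 4338 lower, while scaling on ORFs shifted the median of all genes by 0.49 and gave 5189 higher and 2927 lower.

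Ribo-depleted libraries of enp1 (n = 2) and control (n = 2) were compared with the same question. RPS3 fell by 2.53 ± 0.0415 on the log2 scale, KRR1 by 1.91 and HIS4 by 1.80. PAB1 fell by 0.83, and NAB2 rose by 0.71 and HRP1 by 1.47. CUT_XII_109242_109666 rose by 3.88, and snR189 fell by 1.93 ± 0.0851, from 103.1 to 27.09 CPM. Of 136 ribosomal protein genes 127 fell and 5 rose (127 and 6 adjusted over the list alone), median −1.40 (camera adjusted p = 4.47e-24; adjusted p = 0.244 with an estimated correlation). Of 41 ribosome biogenesis genes 32 fell and 4 rose (33 and 4 adjusted over the list alone), median −0.59, with an adjusted p of 1.12e-05 (adjusted p = 0.0655 with an estimated correlation). All 9 histone genes fell, HTB1 by 1.59, the same adjusted over the list alone, with an adjusted p of 0.000153 (adjusted p = 0.136 with an estimated correlation). Of 57 snoRNAs 34 fell and 6 rose, the same adjusted over the list alone, with an adjusted p of 0.00512 (adjusted p = 0.431 with an estimated correlation). Of 735 CUTs 311 rose and 94 fell (292 and 84 adjusted over the list alone), with a median of 0.87, or 1.01 at the bound, and an adjusted p of 0.000249. Phosphate starvation genes, which had fallen in oligo d(T) RNA, went both ways in ribo-depleted RNA: 4 rose, PHO5, an acid phosphatase gene that overlaps another feature, by 1.52, and 4 fell, the same adjusted over the list alone. That list was not called, with an adjusted p of 0.943 and a median of 0.22 that was −0.01 without enp1 replicate 2 and −0.09 without control replicate 2.

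Of 19 mating pheromone genes 16 rose and 1 fell in ribo-depleted enp1, the same adjusted over the list alone, with an adjusted p of 0.000425 that held with an estimated correlation. The a-specific members STE2 and MFA2, an a-pheromone gene, rose by 5.85 and 9.46, and MF(ALPHA)1 fell by 10.87. In all 3681 features were higher and 3909 lower. Scaling on ORFs shifted the median of all genes by 0.296 and gave 4655 higher and 2938 lower.

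Ribo-depleted libraries of srm1 (n = 2) and control (n = 2) followed. HSP78 rose by 3.39 ± 0.0312 on the log2 scale, from 260.5 ± 2.15 to 2723 ± 31.8 CPM, and HSP42, a small heat shock protein, by 2.58. HRP1 rose by 4.04 ± 0.038 and NAB2 by 1.51, while PAB1 fell by 2.07 ± 0.0341. RPN4, the transcription factor of the proteasome genes, rose by 2.08 ± 0.0213. RPS20 fell by 3.64 ± 0.0367, KRR1 by 3.39, RPA135, of RNA polymerase I, by 2.09, and HIS4 by 4.20. CLN2 fell by 3.00.

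Of 24 heat shock chaperone genes 18 rose and 5 fell in ribo-depleted srm1, with an adjusted p of 0.00405 (adjusted p = 0.357 with an estimated correlation). Of 136 ribosomal protein genes 124 fell and 9 rose (124 and 10 adjusted over the list alone), median −1.61 (camera adjusted p = 6.2e-21; adjusted p = 0.357 with an estimated correlation). Of 41 ribosome biogenesis genes 34 fell and 5 rose, median −1.14, with an adjusted p of 5.84e-07. Of 19 amino acid biosynthesis genes 15 fell and 2 rose, with an adjusted p of 0.00405 (adjusted p = 0.357 with an estimated correlation). Except for the ribosomal protein genes, the counts were the same adjusted over the list alone. Of 735 CUTs 301 rose and 123 fell (284 and 113 adjusted over the list alone), with a median of 0.69, or 0.85 at the bound, and an adjusted p of 0.0234. That call ended with median-ratio scaling (0.80), with scaling on ORFs (1.02), and without srm1 ribo-depleted replicate 2 (0.66). Of 11 phosphate starvation genes, of which 8 had fallen in oligo d(T) RNA, 3 fell and 7 rose, the same adjusted over the list alone, and PHO89 rose by 1.02. That list was not called, with a median of 1.02 and an adjusted p of 0.224. The rRNA share stood at 4.594 ± 4.23% in srm1 and 0.6349 ± 0.0675% in the control, and the wide spread came from srm1 replicate 2. MFA2 rose by 7.25 and MF(ALPHA)1 fell by 6.99 beside these groups. In all 4165 features were higher and 3904 lower, while scaling on ORFs shifted the median of all genes by 0.332 and gave 5079 higher and 3053 lower.

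Ribo-depleted libraries of dis3 (n = 2), with an allele of the catalytic exosome subunit, were compared with the control (n = 2). CUT_XII_109242_109666 rose by 3.09 ± 0.0861 on the log2 scale, from 2.664 to 22.85 CPM, and the box C/D snoRNA snR77 by 1.91. ETS1-1, the external spacer of the ribosomal RNA precursor, rose by 2.37, from 3570 ± 118 to 18400 ± 398 CPM, and overlaps another feature. PAB1 fell by 0.86 ± 0.0331 and NAB2 rose by 0.50. RPS3 fell by 2.55, RPL6A by 1.55, HIS4 by 2.79 and KRR1 by 1.71.

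Of 735 CUTs 368 rose and 51 fell in dis3 (360 and 50 adjusted over the list alone), with a median of 1.51, or 1.5 at the bound, and an adjusted p of 4.66e-11. Among CUTs that overlap no other feature 67 rose and 1 fell. Of 136 ribosomal protein genes 125 fell and 7 rose (125 and 9 adjusted over the list alone), with an adjusted p of 2.19e-21 (adjusted p = 0.233 with an estimated correlation). All 32 proteasome genes fell, median −0.65 (camera adjusted p = 3.87e-08; adjusted p = 0.108 with an estimated correlation). All 9 histone genes fell, HHT2 by 1.29, median −1.10 (camera adjusted p = 0.000189; adjusted p = 0.11 with an estimated correlation). Of 24 heat shock chaperone genes 3 rose and 20 fell, among the latter HSP104 by 1.08, with an adjusted p of 0.000133 (adjusted p = 0.186 with an estimated correlation). Of 11 phosphate starvation genes 7 rose and 1 fell, median 1.06, with an adjusted p of 0.00969 (adjusted p = 0.108 with an estimated correlation). The last 4 lists had the same counts adjusted over the list alone. Of 19 mating pheromone genes 13 rose and 2 fell, the same adjusted over the list alone, with an adjusted p of 0.00306 (adjusted p = 0.0542 with an estimated correlation), and among them STE2 rose by 5.58 and MFA2 by 8.90. In all 3169 features were higher in dis3 and 4095 lower. Scaling on ORFs shifted the median of all genes by 0.418 and gave 4730 higher and 2444 lower.

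Ribo-depleted libraries labelled rrp6 deletion (n = 2), which lack the nuclear exonuclease of the exosome per the labels, were compared with the control (n = 2). Among box C/D snoRNA features, snR76 rose by 3.34 ± 0.0992 on the log2 scale, from 10.65 ± 0.285 to 107.7 ± 3.34 CPM, and snR77 by 3.63. The H/ACA snoRNA snR85 rose by 3.07 ± 0.0858 and CUT_XII_109242_109666 by 3.02. PHO89 rose by 1.63 and VTC3 by 1.60. TPS2 fell by 2.01, HSP42 by 1.55 and HIS4 by 1.92. NAB2 rose by 0.61, and PAB1 stood at −0.16, which turned to 0.16 with scaling on ORFs.

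Of 57 snoRNAs 30 rose and 7 fell in rrp6 deletion, with a median of 0.69 and an adjusted p of 0.0012 (adjusted p = 0.354 with an estimated correlation). Of 28 box C/D snoRNAs 19 rose and 1 fell, median 1.42 (camera adjusted p = 0.000195; adjusted p = 0.0931 with an estimated correlation). Of 735 CUTs 328 rose and 51 fell (314 and 48 adjusted over the list alone), with a median of 1.15, or 1.261 at the bound, and an adjusted p of 3.13e-08. Of 11 phosphate starvation genes 10 rose, median 2.01, with an adjusted p of 0.000129. Of 20 general stress genes 17 fell and 1 rose, median −2.12 (camera adjusted p = 3.07e-07; adjusted p = 0.0931 with an estimated correlation). Of 136 ribosomal protein genes 119 fell and 8 rose (120 and 10 adjusted over the list alone), with a median of −0.52 and an adjusted p of 1.04e-12 (adjusted p = 0.389 with an estimated correlation). All 9 histone genes fell, HHT2 by 1.11 (camera adjusted p = 0.00021; adjusted p = 0.0931 with an estimated correlation). For snoRNAs, phosphate, stress and histone genes the counts were the same adjusted over the list alone. Of 41 ribosome biogenesis genes 28 rose and 2 fell (29 and 2 adjusted over the list alone), and NOG1, a GTPase of 60S assembly, rose by 0.46. That list had a median of 0.29 and a mean of −0.09, with an adjusted p of 8.46e-05 (adjusted p = 0.0931 with an estimated correlation). The alpha-specific gene MF(ALPHA)1 fell by 10.73 and LYS2 rose by 9.64 beside these groups. In all 3224 features were higher and 3760 lower, while scaling on ORFs shifted the median of all genes by 0.313 and gave 4577 higher and 2471 lower.

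**Figure D2:**
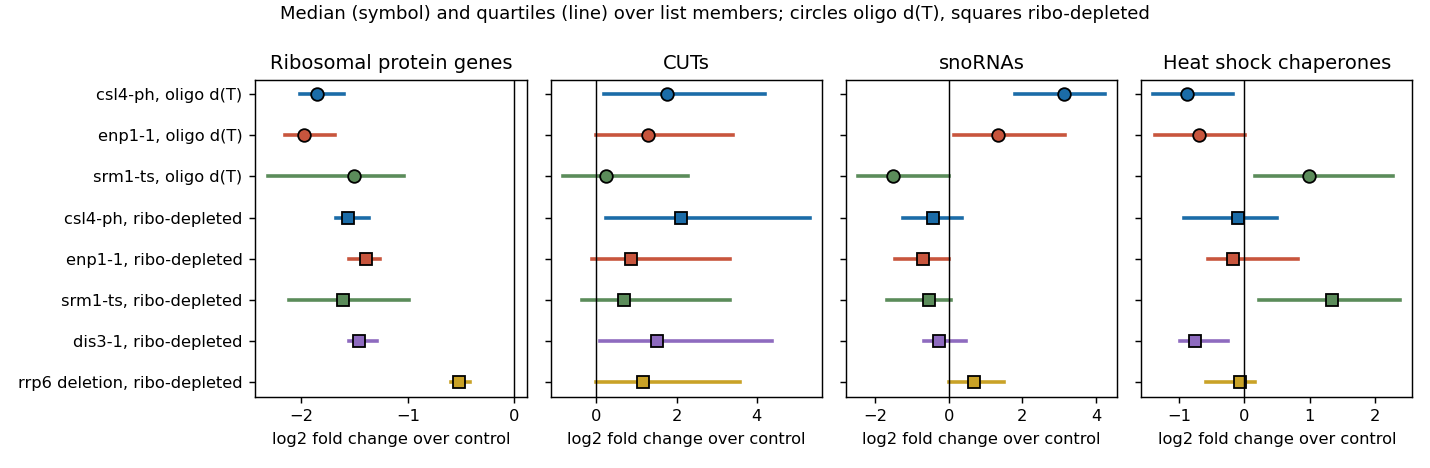
Median log2 fold change over control for ribosomal protein genes, CUTs, snoRNAs and heat shock chaperones (1 panel each; symbols are medians and lines span the quartiles of the list members; circles oligo d(T), squares ribo-depleted). Ribosomal protein medians lie below 0 in every strain shown, and snoRNAs range from 3.12 in csl4 to −1.52 in srm1 in oligo d(T) RNA.

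**Figure D3:**
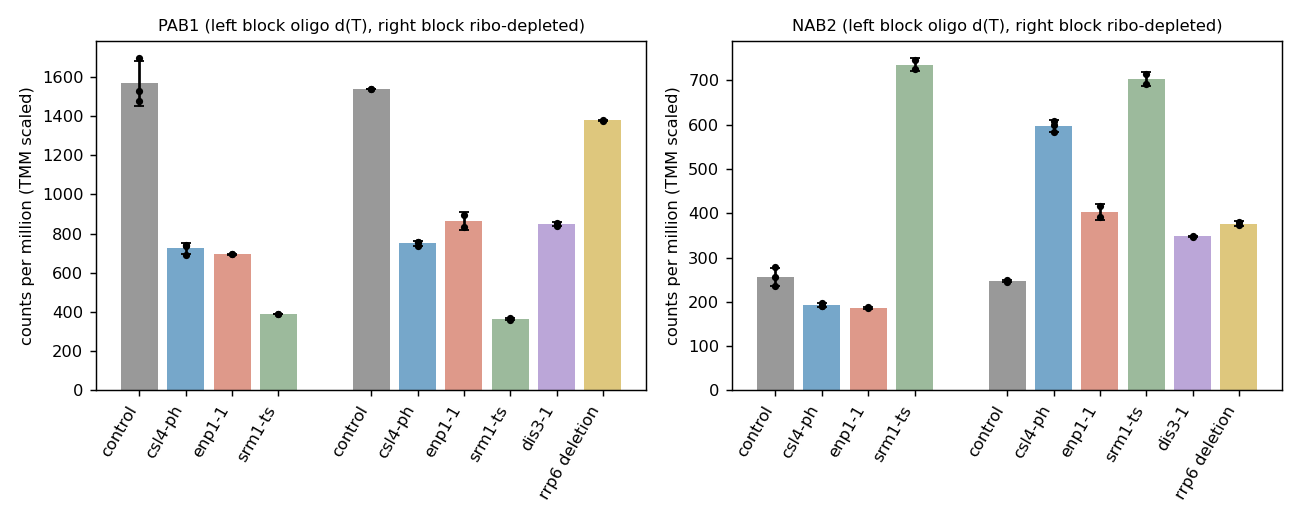
PAB1 and NAB2 in CPM by strain, with bars at the mean, error bars of 1 SD and points for single libraries. NAB2 in csl4 lies below the control in oligo d(T) RNA (193.3 against 256.7 CPM) and above it in ribo-depleted RNA (596.9 against 246.6 CPM).

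Whether a strain's change differed between oligo d(T)-selected and ribo-depleted RNA was tested as an interaction in 1 fit of both tables, in which selection and sequencing table are the same split of the libraries. In csl4 the change in oligo d(T) RNA minus that in ribo-depleted RNA was −1.70 ± 0.0626 on the log2 scale for NAB2 and 4.49 ± 0.133 for snR189. It was −1.34 for HTA2, −2.81 for RPL8A, of the large ribosomal subunit, and 1.98 for UTP20, of small-subunit assembly. Of 58 snoRNAs 40 had a higher change in oligo d(T) RNA and 2 a lower one (43 and 2 adjusted over the list alone), median 3.30, with an adjusted p of 1.64e-12. All 11 phosphate starvation genes had a lower one, the same adjusted over the list alone, PHO89 by 2.59, with an adjusted p of 1.99e-07. Of 136 ribosomal protein genes 100 had a lower and 9 a higher change (105 and 10 adjusted over the list alone), median −0.28 (camera adjusted p = 7.77e-09; adjusted p = 0.447 with an estimated correlation). Of 10790 features 2987 had a higher change and 2928 a lower one, and median-ratio scaling shifted the median of all genes by −0.12.

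For enp1 the difference was −1.19 for NAB2, −1.52 for HRP1, 2.51 for snR189 and 3.68 for ARG3, of arginine biosynthesis. Of 58 snoRNAs 32 had a higher change in oligo d(T) RNA and 2 a lower one (34 and 2 adjusted over the list alone), with an adjusted p of 1.69e-10. All 11 phosphate starvation genes had a lower one, the same adjusted over the list alone, PHO89 by 2.85 (camera adjusted p = 2.07e-07). For ribosomal protein genes 120 of 136 had a lower change and 5 a higher one (122 and 5 adjusted over the list alone), with an adjusted p of 4.59e-17 (adjusted p = 0.206 with an estimated correlation). In all 2464 features had a higher change and 3257 a lower one. For srm1 the difference was −3.69 ± 0.204 for snR76 and −2.18 for snR85, and 2.24 for RRP5, of ribosome assembly. NAB2 differed by −0.05 (adjusted p = 0.617). Of 11 phosphate starvation genes 10 had a lower change (11 adjusted over the list alone), PHO89 by 2.68, with an adjusted p of 2.21e-05. Of 41 ribosome biogenesis genes 27 had a higher change and 4 a lower one, the same adjusted over the list alone, and that of NOG1 was higher by 1.65 (camera adjusted p = 2.47e-06; adjusted p = 0.062 with an estimated correlation). In all 2426 features had a higher change and 2992 a lower one.

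In 3′ tag libraries with the empty vector, csl4 (n = 3) was compared with the control (n = 3). CUT_XI_571070_571206 rose by 7.68 ± 0.332 on the log2 scale, from 0.7296 ± 0.86 to 164.4 ± 14.3 CPM, and snR17b, a copy of the U3 snoRNA gene, by 2.37 ± 0.234. NAB2 rose by 1.45 ± 0.124, from 71.91 ± 4.42 to 196.7 ± 9.5 CPM (adjusted p = 1.13e-07). PAB1 stood near the floor, at 1.857 against 2.006 CPM. HTA2 rose by 2.74 ± 0.188, from 60.35 ± 18.7 to 403.3 ± 51.8 CPM. HIS4 fell by 2.82 ± 0.164, ARG4, of arginine biosynthesis, by 1.83 and RPL15A by 1.47. Of 606 CUTs 375 rose and 51 fell (384 and 60 adjusted over the list alone), with a median of 2.98, or 2.501 at the bound, and an adjusted p of 1.51e-11. Of 97 ribosomal protein genes 40 fell and 5 rose (39 and 5 adjusted over the list alone), with a median of −0.95 and an adjusted p of 6.87e-08 (adjusted p = 0.452 with an estimated correlation). Of 36 snoRNAs 22 rose and 4 fell (23 and 4 adjusted over the list alone), with an adjusted p of 0.015 (adjusted p = 0.4 with an estimated correlation), a call that ended without the filter on low counts, at 1.30. In all 2048 features were higher and 980 lower, and scaling on ORFs shifted the median of all genes by 0.186.

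In the same libraries enp1 (n = 3) was compared with the control (n = 3). CUT_XVI_622706_623218 rose by 5.14 ± 0.285 on the log2 scale, from 1.327 to 47.99 CPM, and the box C/D snoRNAs snR57 by 6.27 ± 0.402 and snR52 by 3.04 ± 0.249. NAB2 rose by 0.74 ± 0.124. HIS4 fell by 2.84, RPL15A, of the large ribosomal subunit, by 1.17 and HSP60, the mitochondrial chaperonin, by 1.51. LYS2 was at least 62.58-fold higher. Of 606 CUTs 294 rose and 39 fell (311 and 41 adjusted over the list alone), with a median of 1.85, or 1.36 at the bound, and an adjusted p of 6.68e-09. Of 36 snoRNAs 22 rose (23 rose and 1 fell adjusted over the list alone), with an adjusted p of 0.000764 (adjusted p = 0.175 with an estimated correlation). Of 97 ribosomal protein genes 33 fell and 2 rose, the same adjusted over the list alone, median −0.69 (camera adjusted p = 1.22e-07; adjusted p = 0.468 with an estimated correlation). In all 1593 features were higher and 883 lower, while scaling on ORFs shifted the median of all genes by 0.191 and gave 1855 higher and 602 lower.

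The Pab1 vector was compared with the empty vector within each strain (n = 3 against 3) to ask what the added Pab1 changed. PAB1 itself rose in the control by 3.21 ± 0.381 on the log2 scale, from 2.006 ± 0.692 to 19.29 ± 2.62 CPM (adjusted p = 0.000566). In csl4 it rose by 4.22 ± 0.361, from 1.857 ± 0.733 to 36.41 ± 9.96 CPM, and in enp1 by 3.11 ± 0.352, from 2.336 ± 0.969 to 20.97 ± 4.93 CPM. The empty-vector levels lay near the floor, which is 1.01 to 1.94 CPM in 3′ tags. PAB1 stood at 1537 CPM in ribo-depleted control RNA, so these folds rest on a baseline that 3′ tags barely measured. The feature ST4652 rose by 5.17 in the control, 2.32 in csl4 and 4.41 in enp1. It overlaps another feature and lies close to PAB1, at V 509818–510218 beside V 510373–512106. Whether its reads come from the vector was not tested. In the control strain 14 features were higher and 11 lower (DESeq2 gave 43 and 53), and the 25 calls became 101 with the compared groups alone and 11 without the filter on low counts. In csl4 15 were higher and 11 lower (DESeq2 gave 65 and 131), and the 26 calls became 2 with the compared groups alone and 16 without that filter. Leaving out any 1 library of these pairs left 7 to 14 calls in the control. In csl4 it left 4 to 10 calls, save for 211 without csl4 Pab1 replicate 1.

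In enp1 the Pab1 vector went with 109 features higher and 315 lower, and these 424 calls became 76 with the compared groups alone and 658 with DESeq2. CUTs fell, 70 of 606 lower and 8 higher (109 and 9 adjusted over the list alone), with a median of −0.74, or −0.72 at the bound, and an adjusted p of 3.43e-06 (adjusted p = 0.00316 with an estimated correlation). ENA2, a sodium pump gene from a family of near-identical copies, fell by 3.81 ± 0.402, from 106 ± 49.5 to 7.191 ± 6.14 CPM. RPL31B, of the large ribosomal subunit, rose by 0.66. All 18 features from V 7230 to V 17845, chosen after their values were seen, were at 0 counts in the 3 enp1 Pab1 libraries, while the 3 enp1 empty-vector libraries held 540 counts there and the control Pab1 libraries 352. This segment held 7 of the 315 lower features and 3 of the 70 lower CUTs. NAB2 stood at −0.53 with an adjusted p of 0.0163, and this call ended without enp1 empty-vector replicate 1 or 3 and without enp1 Pab1 replicate 1 or 3. Without enp1 Pab1 replicate 3 the 424 calls fell to 210, and without enp1 Pab1 replicate 1, enp1 empty-vector replicate 2 and enp1 empty-vector replicate 3 to 272, 265 and 282.

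Whether the effect of the Pab1 vector differed from that in the control was tested as an interaction. For csl4 the test called 2 features, both lower: ST4652, with a difference of −2.85 (adjusted p = 7.57e-05), and NUT0793 (adjusted p = 0.0146), named after its values were seen. ST4652 stood at 170.2 CPM in csl4 and 189.7 CPM in the control with the Pab1 vector. With the empty vector it stood at 34.11 and 5.29 CPM. PAB1, near the floor with the empty vector, had a difference of 1.01 (adjusted p = 0.74). The count was 1 without control empty-vector replicate 1 or control Pab1 replicate 1, 4 without control empty-vector replicate 3, control Pab1 replicate 2 or 3 or csl4 empty-vector replicate 3, and 5 without csl4 Pab1 replicate 1. With the compared groups alone the count was 1, and DESeq2 gave 32. For enp1 it called 57 features, 9 higher and 48 lower, of which 5 lay in that segment of chromosome V. The count was 33 with the compared groups alone, 37 without the filter on low counts and 157 with DESeq2. PAB1, near the floor with the empty vector, had a difference of −0.10 (adjusted p = 0.999). CUTs were lower, 10 of 606 lower and 1 higher (18 and 1 adjusted over the list alone), with a median of −0.55 and an adjusted p of 1.34e-05 (adjusted p = 0.00618 with an estimated correlation). Of 97 ribosomal protein genes 3 were higher (5 adjusted over the list alone), median 0.53 (camera adjusted p = 2.26e-06; adjusted p = 0.707 with an estimated correlation). Without control empty-vector replicate 1 the enp1 count was 18, and it was 19 to 34 without control empty-vector replicate 2, any control Pab1 replicate, enp1 empty-vector replicate 2 or enp1 Pab1 replicate 3.

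Changes shared between mutants were counted within each table, where the mutants share their control libraries. In oligo d(T) RNA csl4 and enp1 had 3169 features higher in both and 3442 lower in both, against 1511 and 1599 if calls were independent, and 418 in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.734 and a covariance of 6.26. Unchanged groups simulated against the same controls gave 0.482 and 0.322. For csl4 and srm1 the counts were 2503 and 2693, against 1570 and 1565, with 1563 opposite, r = 0.478 (0.481 simulated) and a covariance of 4.08 (0.331 simulated). For enp1 and srm1 they were 2549 and 2615, against 1553 and 1522, with 1554 opposite, r = 0.507 (0.44 simulated) and a covariance of 4.43 (0.332 simulated).

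In ribo-depleted RNA csl4 and dis3 shared 2787 features higher and 3530 lower, against 1123 and 1682 if independent, with 267 opposite, r = 0.736 across genes (0.57 simulated) and a covariance of 6.34 (0.43 simulated). For dis3 and rrp6 deletion the counts were 2470 and 3151, against 967.1 and 1458, with 424 opposite, r = 0.784 (0.536 simulated) and a covariance of 5.75 (0.44 simulated). For csl4 and rrp6 deletion they were 2427 and 2958, against 1142 and 1544, with 799 opposite, r = 0.652 (0.591 simulated) and a covariance of 5.37 (0.451 simulated). For csl4 and enp1 they were 2943 and 3408, against 1304 and 1605, with 467 opposite, r = 0.775 (0.596 simulated) and a covariance of 6.72 (0.464 simulated). For csl4 and srm1 they were 2604 and 2886, against 1476 and 1603, with 1362 opposite, r = 0.654 (0.597 simulated) and a covariance of 6.35 (0.471 simulated). In 3′ tags csl4 and enp1 shared 1344 features higher and 620 lower, against 512.2 and 135.9, with 12 opposite, r = 0.834 (0.516 simulated) and a covariance of 4.48 (0.38 simulated). The simulated groups had at most 0 calls in the same direction over 5 draws. They were made with no change, so this number was bound to be low and is no measure for groups that do change. The simulation also holds no difference of strain background. In every table it leaves out features at 0 counts in the control. In the data these features enter r and covariance with log2 fold changes that are not held to a bound. NUT0820 in ribo-depleted RNA, for example, enters at 15.08 in enp1 and 13.88 in srm1 (9.525 and 8.325 at the bound). How much of each covariance rests on such features was not measured, so its excess over the simulated value is no measure of shared change. Part of each excess over independence may come from the shared controls. Strains that share mating type and markers, such as enp1, srm1 and dis3, also share those differences from the control.

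The same strain was compared across tables, which have different control libraries. For csl4 oligo d(T) and ribo-depleted RNA had 2756 features higher in both and 3261 lower in both, against 1418 and 1731 if independent, with 756 opposite and r = 0.56 across genes. For srm1 they had 3177 and 3062, against 1634 and 1484, with 625 opposite and r = 0.694. For enp1 they had 2730 and 3010, against 1385 and 1521, with 644 opposite and r = 0.443. Against 3′ tags, csl4 oligo d(T) RNA had 1163 higher and 662 lower in both (795.3 and 380.2 if independent) and 592 opposite, r = 0.311, and ribo-depleted RNA 1136 and 700 (697.1 and 415.9), 523 opposite, r = 0.352. For enp1 the oligo d(T) counts were 918 and 597 (641.1 and 324.3), 466 opposite, r = 0.224, and the ribo-depleted counts 838 and 648 (536.3 and 343.8), 401 opposite, r = 0.261. HTA2 in csl4 went opposite ways, at −4.37 in oligo d(T) RNA and 2.74 in 3′ tags, a difference that was not tested.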

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

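Among the tests in this part, the MET17 count, the share of snRNA and the test on the segment of chromosome V were chosen only after the results were seen, as were HMRA1 and the list of haploid-specific genes.

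The effect of a strain differed between oligo d(T)-selected and ribo-depleted RNA at 5915 features for csl4, 5721 for enp1 and 5418 for srm1, each by a test of the interaction. The effect of the Pab1 vector differed between csl4 and the control at 2 features and between enp1 and the control at 57 features, by the same kind of test. For csl4, 8 of 100 splits of the libraries gave as many calls, with a highest of 2 among the other splits, so chance is not excluded. For enp1, 1 of 100 splits, the real one, gave as many, with a highest of 41 among the others. Splits that mix the vector groups within enp1, where the vector itself went with 424 calls, are bound to call few features. The share of splits therefore cannot decide whether chance gave the enp1 count. The splits were not run in other settings, where the count was 33 with the compared groups alone, 37 without the filter on low counts and 157 with DESeq2. It was also under 41 without some single libraries: 18, 27 and 28 without control empty-vector replicate 1, control empty-vector replicate 2 and control Pab1 replicate 1, 20 and 19 without control Pab1 replicates 2 and 3, 34 and 38 without enp1 empty-vector replicates 2 and 3, and 26 without enp1 Pab1 replicate 3.

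In comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05, and 1 split of each, the real one, gave as many calls. The real counts and the highest of the other splits were 8146 and 1 for csl4 in oligo d(T) RNA, 3028 and 1 for csl4 in 3′ tags, and 2476 and 1 for enp1 in 3′ tags. For the Pab1 vector they were 25 and 3 in the control, 26 and 1 in csl4, and 424 and 8 in enp1. Every other split mixes the compared groups and is bound to call few features where these differ. The low counts of the other splits therefore cannot decide whether chance gave the calls.

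Mating-type and marker genes differed from the control in enp1, srm1, dis3 and rrp6 deletion. The a1 transcript HMRA1, at 0 counts in the control, was at least 18.1-fold higher in srm1, at least 28.93-fold in enp1 and at least 43.75-fold in dis3 against 3 counts per control library (lowest log2 bound 4.18), which is consistent with a MATa parent of these strains and a MATalpha parent of the control. In rrp6 deletion the median of the haploid-specific genes was −3.36, with 7 of 7 lower, as an a/alpha diploid would give. A haploid that expresses both mating-type cassettes was not tested. In the other mutants the median of this list was also below 0, from −0.14 in dis3 to −1.64 in srm1 in oligo d(T) RNA. In ribo-depleted csl4 it was −0.73, with 5 lower and 2 higher. The highest MET17 count in enp1, srm1 and dis3 was 7, so that a deleted allele may be present, but a loss of expression by the mutations themselves is not excluded. Effects of the mutations and of strain background therefore cannot be separated in these 4 strains for any gene, including those outside mating type and these markers.

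snoRNAs were higher in csl4 in oligo d(T)-selected RNA. The lowest median over 3 scalings was 3.12, which argues against scaling as the cause. The 11 snoRNAs that overlap no other feature had a median of 2.77, with 7 called higher and 0 lower. This argues against reads divided between overlapping features as the cause of the whole rise. Among them the 8 box C/D snoRNAs had a median of 1.62, with 4 higher, and the 3 H/ACA snoRNAs a median of 3.16, with 3 higher. A larger carry-over of RNA without poly(A) tails would bring spliceosomal snRNAs along with snoRNAs at their ratio in ribo-depleted csl4 RNA. The snRNA share rose from 0.006594% to 0.02758%, which is 0.0398 of the rise needed (0.039 to 0.0409 over the 3 csl4 libraries), and this argues against carry-over as the cause of the whole rise. The snoRNA share was 32.3 times that of the control, the snRNA share 4.18 times and the ribosomal RNA share 2.21 times, so that a smaller part from carry-over stays open. In 3′ tags with the empty vector 22 of 36 snoRNAs rose in csl4 and 4 fell. The csl4 change was higher in oligo d(T) than in ribo-depleted RNA for 40 of 58 snoRNAs and lower for 2. Tails on snoRNAs in the exosome mutant stay a hypothesis that was not tested. The tables, that of 3′ tags included, hold counts per feature and give neither the position of 3′ ends nor tails. Reads across the 3′ ends of snoRNAs would test it.

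CUTs were lower with the Pab1 vector in enp1. Leaving out 1 of the 6 libraries gave a median of at most −0.65, thinning the libraries to the same total outside the ribosomal DNA gave −0.71, and the median of CUTs lay 0.74 below that of ORFs (a difference of −0.74), which argues against a single library, that total and scaling as the cause. At the left end of chromosome V 18 neighbouring features (V 7230 to V 17845) were at 0 counts in the 3 enp1 Pab1 libraries and took 540 counts in the 3 enp1 empty-vector libraries, and 8 of them had at least 10 counts there, against at most 2 in any other such run of the Pab1 and empty-vector pairs. This is consistent with a segment lost in that strain, a hypothesis from the same values. The segment held 3 of the 606 tested CUTs and 3 of the 70 lower ones, so that 67 lower CUTs lay elsewhere. Other differences between the clones cannot be told apart from an effect of added Pab1, since the share of the segment was 0 in each enp1 Pab1 library and the clone goes with the vector.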

How the results depend on the processing

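All alternatives here were planned, and no test was chosen after the data were seen. Counts of calls for each mutant against the control and for the selection interactions stayed within 1.5 times under every alternative tried. The other counts moved, and the cause was not tested. Without the filter on low counts the Pab1 calls were 11 in the control (25 in the main setting) and 16 in csl4 (26), and the enp1 and Pab1 interaction had 37 (57). With the compared groups alone they were 101 in the control, 2 in csl4 and 76 in enp1 (424), and 1 and 33 for the csl4 (2) and enp1 interactions, from fits with fewer libraries. DESeq2 gave 96, 196 and 658, and 32 and 157 for the interactions. Leaving out 1 library gave 7 to 14 in the control, 4 to 211 in csl4 and 210 to 342 in enp1, and 1 to 5 and 18 to 66 for the interactions. Where a group was left with 1 library, it was assumed to vary like the others. Of 454 list tests 156 were called, and 51 with an estimated correlation.

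The log2 fold change of CSL4 in csl4 turned to 0.32 with scaling on ORFs in oligo d(T) RNA, and to 0.44 with scaling on ORFs and 0.14 with the compared groups alone in ribo-depleted RNA. Leaving out 1 library in oligo d(T) RNA gave −0.0411 to 0.143, the highest without control replicate 1. PAB1 in rrp6 deletion turned to 0.16 with scaling on ORFs. CSL4, not called in the main setting, was called in these reversed cases, and the cause was not tested.

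Shared changes limited to calls of at least 2-fold were 3433 for csl4 and enp1, 2529 for csl4 and srm1, and 2639 for enp1 and srm1 in oligo d(T) RNA. In ribo-depleted RNA they were 2624 for csl4 and dis3, 2007 for csl4 and rrp6 deletion, 2036 for dis3 and rrp6 deletion, 3021 for csl4 and enp1, and 2730 for csl4 and srm1. A stricter threshold leaves fewer calls by construction.

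With replicate block, csl4 had 7970 calls in oligo d(T) RNA and the Pab1 vector 17 in the control and 374 in enp1, and all counts stayed within 1.5 times. DIS3 in dis3 was called with this block, at 0.06. Same-numbered libraries of directly compared groups correlated at −0.186 to 0.0973 over 32 pairs. Over all groups of a table the range was −0.0948 to 0.0398 in oligo d(T) RNA, −0.0203 to 0.0654 in ribo-depleted RNA and −0.238 to 0.317 in 3′ tags, and not every library correlated best with its own number, so the numbers are not taken to pair them. Of 2638 values for 225 results on single genes, 2501 stayed on the same side, 86 lost and 15 gained a call, 31 moved and 5 reversed. Of 3022 values for 234 list results, 2780 stayed the same, 163 lost and 27 gained a call, and 52 moved. The 3′ tag table was the shallowest, with 472470 to 837691 counts outside the ribosomal DNA. There 25.4% of simulated 2-fold changes between csl4 and control were called, and depth was not separated from other limits.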

Other observations

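The subsets of features that overlap no other feature were chosen only after the tables were seen, while the gene lists were fixed beforehand.

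CUTs that overlap no other feature were mostly higher in every mutant. In oligo d(T) RNA 85 of 90 were higher in csl4, with a median of 2.77, 83 in enp1, with a median of 2.61, and 65 higher and 6 lower in srm1. In ribo-depleted RNA, of 87 such CUTs, 63 were higher and 4 lower in csl4, with a median of 2.19, 57 and 6 in enp1, with a median of 2.00, and 65 and 4 in srm1, with a median of 2.39. In dis3 67 were higher and 1 lower, with a median of 2.42, and rrp6 deletion had the same counts and a median of 2.30. The 11 snoRNAs that overlap no other feature went apart between strains: 10 were higher in enp1 in oligo d(T) RNA, with a median of 3.13, and 5 were lower in srm1, with a median of −1.37. In ribo-depleted RNA 9 were higher in rrp6 deletion, with a median of 1.67, and 7 were higher and 2 lower in dis3, with a median of 1.30 against −0.26 over all tested snoRNAs. In csl4 2 were higher and 5 lower, with a median of −0.33. CUT features took 0.4307 ± 0.0162% of the counts in the control in oligo d(T) RNA, 0.9237 ± 0.0188% in csl4, 0.8305% in enp1 and 0.6165% in srm1.

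In dis3 14 of 19 amino acid biosynthesis genes fell and 1 rose, with a median of −0.92 (camera adjusted p = 0.000133; adjusted p = 0.179 with an estimated correlation). Ribosome biogenesis genes in dis3 fell at 33 of 41 members with a median of −0.38, but the call ended at 0.04 with scaling on ORFs. In rrp6 deletion all 32 proteasome genes fell, with a median of −0.44 (camera adjusted p = 2.6e-07; adjusted p = 0.0931 with an estimated correlation). In srm1 17 proteasome genes rose and 13 fell in ribo-depleted RNA, and the list was not called, with an adjusted p of 0.441. Of 12 G1/S genes 10 fell and 2 rose in ribo-depleted srm1, with an adjusted p of 0.0234 (adjusted p = 0.132 with an estimated correlation). In ribo-depleted enp1 the amino acid list had a median of −0.57 and a mean of 0.20. These counts were the same adjusted over the list alone.

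Called features that stood at 0 in a group and at 10 CPM or more in the other overlapped another feature in 167 of 167 cases for csl4 in oligo d(T) RNA and in 238 of 239 cases for csl4 in ribo-depleted RNA, against 66.81% and 67.09% of tested features. In 3′ tags these were 175 of 182 cases for csl4, 68 of 75 for enp1 and 5 of 6 for the Pab1 vector in enp1, against 67.2%.

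Of the 10 further lists 5 were called by camera in 0 comparisons: the genes followed by name (lowest adjusted p 0.205, unadjusted p under 0.05 in 1 of 18 comparisons), Nrd1-attenuated mRNAs (0.156, 0 of 18), meiotic genes (0.0603, 1 of 18), selection markers (0.0538, 1 of 11) and rRNA with its spacers (0.0639, 2 of 18). Features numbered with F or R and ST features were each called higher in 7 mutants' comparisons in oligo d(T) or ribo-depleted RNA, that is in all but srm1 in oligo d(T) RNA, with medians of 0.35 to 0.94 and 0.24 to 0.69, and these calls held with an estimated correlation. With scaling on ORFs the ST call ended in enp1 in both tables and in srm1, dis3 and rrp6 deletion, and the F and R call ended in srm1, where both calls also ended without srm1 replicate 2 (medians of 0.69 for F and R features and 0.75 for ST features). Of 18 genes of poly(A) binding and mRNA export 12 fell and 2 rose in csl4 in oligo d(T) RNA, the same adjusted over the list alone, with an adjusted p of 0.0409 (adjusted p = 0.225 with an estimated correlation), a call that ended without csl4 replicate 2 or 3, at −0.69 and −0.70, and with scaling on ORFs, at −0.36. Of 22 genes of the RNA exosome and cofactors 11 rose and 3 fell in rrp6 deletion, the same adjusted over the list alone, with an adjusted p of 0.0481 (adjusted p = 0.354 with an estimated correlation), which ended without rrp6 deletion replicate 1 or either control replicate, at 0.19 to 0.21. In csl4 12 of them had a higher change in oligo d(T) than in ribo-depleted RNA and 1 a lower one, the same adjusted over the list alone, with an adjusted p of 0.00253 (adjusted p = 0.0704 with an estimated correlation). All 6 tested other stable noncoding RNAs rose in csl4 in 3′ tags, the same adjusted over the list alone, with an adjusted p of 0.0458 (adjusted p = 0.223 with an estimated correlation), and that call ended without control empty-vector replicate 1 or 2 or csl4 empty-vector replicate 1, at 3.87 to 3.98, and with the compared groups alone, at 2.52.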
